A study of Homo sapiens with 6 samples.

How the data were processed

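Gene expression was measured on 6 single-colour Affymetrix arrays of HCT116 cells, 1 sample per array, from total RNA extracted with a column kit and labelled with biotin by in vitro transcription, per the labels. The deposited table holds signal intensity for 54675 probe sets, on a linear scale; the submitters made these values with MAS5, whose version is not given. The 2% trimmed mean of each array lay between 500.06 and 500.08, so the arrays had been scaled to a common level by the authors and the signals were used as deposited. All 6 columns of values were mapped to a sample. Depth does not apply to arrays, and their number limits the precision.

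Probe sets were named through the platform annotation and a current gene table used for names alone. Of the probe sets 62 were controls, 41091 had 1 gene, 1801 several and 11721 none; 54 with 1 gene had a gene identifier absent from that table. Probe sets with several genes were tested but not named. Signals were taken as log2(signal + 11.24), where 11.24 is the 10th percentile of all signals. Probe sets above the array median on at least 2 of the 6 arrays were kept, without the control probe sets, which left 37601, of which 30269 had 1 gene. The 16088 genes were each read through the probe set with the highest mean log2 signal.

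Groups followed the source names in the labels: parental 2, PCLKC 2, PCLKC-GFP 1 and GFP 1. Differences were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. One fit of the 4 groups, with 2 residual and 2.87 prior degrees of freedom, gave PCLKC versus parental, PCLKC-GFP versus GFP, the difference of these effects, GFP versus parental and PCLKC-GFP versus PCLKC. Groups of 1 array gave no spread of their own and were assumed to vary like the duplicated groups. A fit of 3 arrays against 3, with 4 residual and 5.39 prior degrees of freedom, compared the arrays labelled PCLKC or PCLKC-GFP with the others, as the labels give them; the array labelled GFP, on the other side, has a CDHR2 signal of 4831. The groups, comparisons, main tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Later changes to the naming rule and tests added afterwards are named where they apply.

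The 29 gene lists hold 582 genes, of which 484 were measured and 7 stood in several lists. Lists with at least 3 measured genes were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a comparison. The estimated correlation and fry were computed beside it. Lists of PCLKC-GFP versus GFP were planned as values and not as tests, and are given without p-values. Camera with an estimated correlation also rests on the few residual degrees of freedom of a fit. Its larger p-values are therefore not an effect of correlation alone. Members were counted past the threshold over all genes and adjusted over the list alone. Named genes were the 10 largest rises and 10 largest falls past the threshold without overlap of the arrays in PCLKC versus parental and in the fit of 3 against 3. They were 5 and 5 in PCLKC-GFP versus GFP, and 3 and 3 elsewhere, taken by smallest p where none passed. Of each list up to 4 members with the smallest p in PCLKC versus parental were named; after the data were seen this was limited to 2 for lists that did not pass. CDHR2, CTNNB1, CDH1, AXIN2, MYC, CCND1, LGALS1 and LGALS3 were always named.

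The fits were tested on simulated data with 50 changed probe sets per size. A log2 change of 4 was recovered for 38% of them in PCLKC versus parental, 6% in PCLKC-GFP versus GFP, 18% in GFP versus parental and 70% in the fit of 3 against 3, and a change of 2 for 6%, 0%, 2% and 32%. Far more probe sets were called in the data, such as 20048 of 37601 in PCLKC versus parental, which makes the adjustment less strict. These shares therefore do not give the recovery in the PCLKC comparisons. The simulated arrays took the spread within the duplicated groups and held no differences between lines. For the fit of 3 against 3 the shares of 70% and 32% may thus be too high. Alternatives were quantile normalization, median centring, no pseudocount or one at the 25th percentile (38.8), no filter or one at the 65th percentile, no mean-variance trend, 1 probe set per gene before the fit, a replicate block, and leaving out each array. Added after the data were seen were division of each array by the geometric mean of its 18 hybridization-control probe sets, and a fit of the parental and GFP arrays alone. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.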

Results

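Transcript levels were measured on 6 Affymetrix arrays of 54675 probe sets, hybridised with biotin-labelled RNA from HCT116 cells, a human colorectal carcinoma line. The labels placed the arrays in 4 groups. They were parental cells (n = 2), cells stably carrying PCLKC (n = 2), cells carrying PCLKC with GFP (n = 1) and cells carrying GFP (n = 1). The labels of the PCLKC-GFP array differ, since its title names PCLKC without GFP while its source gives PCLKC-GFP, which was used. PCLKC, or protocadherin LKC, is the product of CDHR2, a cadherin-family adhesion protein of the brush border of the intestine and kidney. The comparisons asked which transcripts differed between cells with and without PCLKC, and whether the GFP lines gave the same differences. The number of arrays limited the precision, and no array came with counts or depth. Nothing in the labels said that arrays of a group came from separate cultures, so p-values measured the spread between these arrays, which may be technical. All arrays had 2% trimmed mean signals between 500.06 and 500.08, and the median signal lay between 57.9 and 242. No pair of arrays held identical values throughout.

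The single CDHR2 probe set was bright on every array of a PCLKC line. Its signal was 24954 and 18687 on the PCLKC arrays, 29006 on the PCLKC-GFP array, and 56.5 and 107 on the parental arrays. The array labelled GFP read 4831, which was 62.1-fold above the geometric mean of the parental arrays and goes against that label. Directions drawn from the array labelled GFP therefore rest on a label that the CDHR2 signal did not bear out. On the log2 scale the PCLKC arrays exceeded the parental arrays by 7.92 ± 0.37 (SE, n = 2 and 2, adjusted p = 0.00199).

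The arrays of PCLKC lines stood apart from the others in control probe sets and RNA measures as well. The hybridization controls, bacterial transcripts added to each sample, were 13.7-fold brighter on the 3 PCLKC-carrying arrays than on the other 3 (geometric means), with ranges of 50185 to 100564 and 3651 to 6496. The control for Alu, a repeat family of primate genomes, was 29.9-fold lower, at 914 to 3251 against 39045 to 69083. The median signal of 10 probe sets of mitochondrially encoded genes was 128 to 200 on PCLKC-carrying arrays and 12380 to 42953 on the others, a 176-fold difference. The ratio of 3' to 5' signal of ACTB was 0.428 to 0.520 against 1.16 to 2.22, and that of GAPDH 1.61 to 1.71 against 0.900 to 0.925. Across the 37601 probe sets tested, Pearson correlations were 0.697 to 0.717 within the PCLKC-carrying arrays, 0.911 to 0.959 within the others and 0.261 to 0.304 between the sets. These differences coincide with the PCLKC groups, so no PCLKC comparison could be repeated without the arrays concerned.

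**Figure D1:**
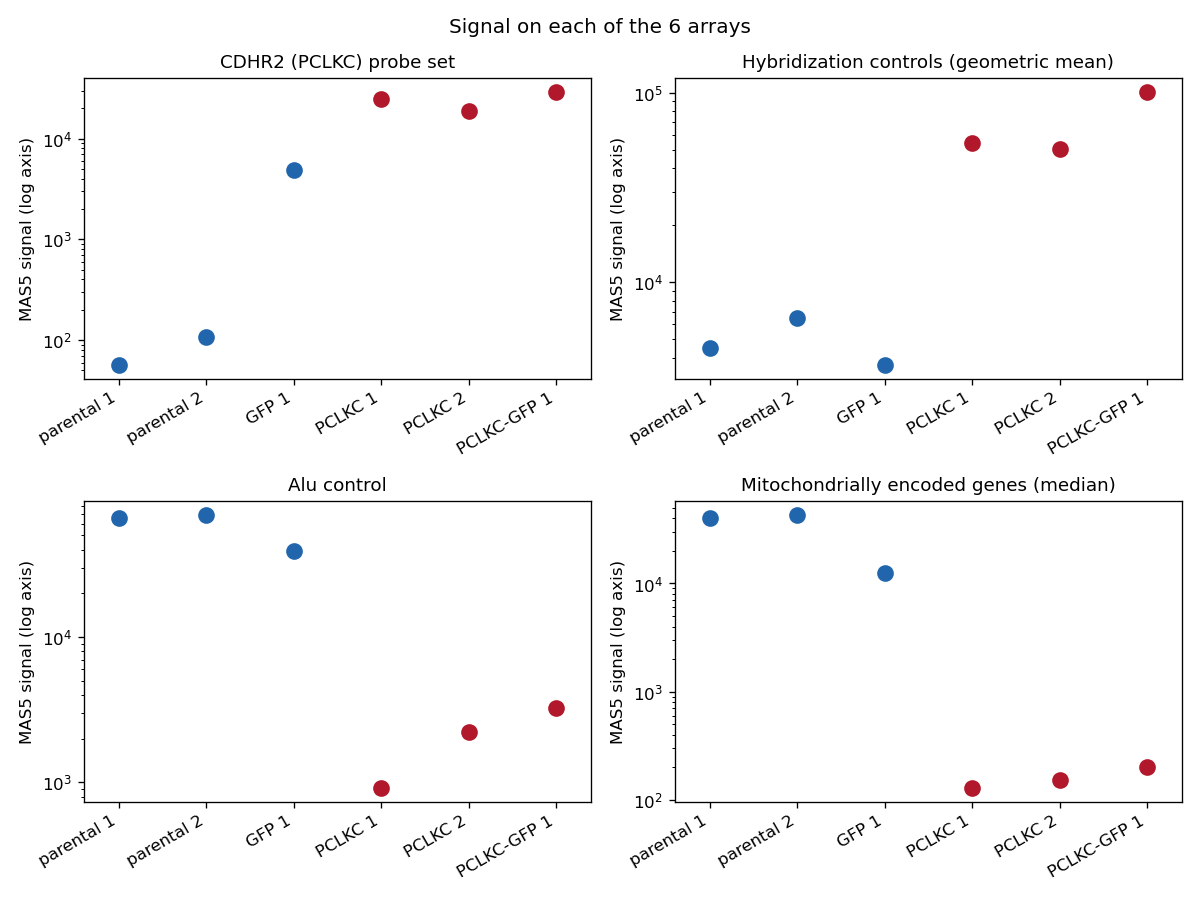
Signal on each array, on log axes, of the CDHR2 probe set, the hybridization controls (geometric mean), the Alu control and the mitochondrially encoded genes (median of 10 probe sets); each point is an array, red for PCLKC-carrying lines and blue for the others. The array labelled GFP reads 4831 for CDHR2, 12380 for the mitochondrially encoded genes against 40322 and 42953 on the parental arrays, and 39045 for the Alu control against 65784 and 69083.

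PCLKC versus parental cells gave its largest rises for STC1, IGFBP7, HDGFL3, CADM1 and POU3F3. STC1, the hormone stanniocalcin, rose by 12.75 ± 0.31 (log2 change ± SE) and IGFBP7, a secreted insulin-like growth factor binding protein, by 12.75 ± 0.30. HDGFL3 rose by 11.43, the adhesion molecule CADM1 by 11.34, the transcription factor POU3F3 by 11.20 and the pseudogene PRORSD1P by 10.49. The transcription factor MAF rose by 10.30, the intermediate filament gene VIM by 9.93 ± 0.47, TMEFF2 by 9.71 and the homeobox gene IRX5 by 9.28. The largest falls were of the mitochondrially encoded COX1 (-11.58 ± 0.27), FAM3C (-9.63), the folate enzyme MTHFD2 (-9.20), IFITM3 (-9.06), EIF3L (-8.83 ± 1.503) and cytochrome c, CYCS (-8.40). ATP5MJ (-8.39), the mitochondrially encoded COX2 (-8.30), NT5C2 (-8.25) and TDP2 (-8.21) followed. Adjusted p-values of these 20 genes ranged from 0.00199 to 0.0101. The naming rule took only genes whose PCLKC and parental arrays did not overlap. The only other probe set of TMEFF2, of CYCS and of NT5C2 had the opposite sign without passing the threshold. The parental arrays read STC1 at 2.81 and 5.96, IGFBP7 at 11.9 and 12.8 and HDGFL3 at 3.55 and 3.73, near or below the pseudocount of 11.24. The sizes and order of such changes therefore depend on the pseudocount: with one of 38.8 they were 11.27 for STC1, 11.63 for IGFBP7 and 9.92 for HDGFL3, and without one 14.67, 13.68 and 13.46. The falls depend on it likewise, as the PCLKC arrays read COX1 at 15.9 and 10.5, FAM3C at 8.90 and 15.5 and TDP2 at 7.36 and 8.56; COX1 was at -10.48 with the larger pseudocount and -12.49 without one.

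In total 20048 of 37601 probe sets differed, 12804 higher and 7244 lower with PCLKC, and among 16088 genes read through their brightest probe set 5920 were higher and 3378 lower. The split depended on the scaling: 63.9% of the calls were higher as deposited, 47.4% after quantile normalization, 25.02% after centring on the median and 3.25% after division by the hybridization controls, a scaling chosen after the data were seen. The median log2 change of all probe sets was 0.82, 0.10, -0.69 and -2.24 under these scalings. The count fell to 0 without parental replicate 1 and to 0 without parental replicate 2, where the spread came from the PCLKC pair alone and the lone parental array was assumed to vary like that pair.

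The oxidative phosphorylation, hypoxia, stress response and heat shock lists passed as lower on the PCLKC arrays, whose mitochondrial medians were 128 and 153 against 40322 and 42953 on the parental arrays. List medians are given relative to the median of all genes, 0.83. Camera does not match a list with other genes of like signal. PCLKC-carrying and other arrays correlated at only 0.261 to 0.304, so bright lists could fall and dim lists rise whatever their function. Of 24 measured oxidative phosphorylation genes 12 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -2.50 (camera, adjusted p = 2.24e-05). With an estimated correlation the list had an adjusted p of 0.413. COX4I1 (-3.99), SDHD (-6.14), COX7C (-3.11) and COX6C (-7.53) were among them. Of 24 hypoxia and glycolysis genes 12 fell and 2 rose (14 and 2 adjusted over the list alone; median -2.27, adjusted p = 0.00255, and adjusted p = 0.413 with an estimated correlation). They included lactate dehydrogenase LDHA (-6.05), ADM (-3.13), P4HA1 (-3.24) and ALDOC (-1.99). The estimated correlation of this list was -0.043, below the preset 0.01. Its larger p in that form thus reflects the 2 residual degrees of freedom and not correlation. That does not extend to the oxidative phosphorylation list, whose estimated correlation was 0.234. Of 26 genes of the unfolded protein and integrated stress response 11 fell and 4 rose (14 and 4 over the list alone; median -2.53, adjusted p = 0.00477, and adjusted p = 0.413 with an estimated correlation). MTHFD2, ASNS (-4.67) and ATF4 (-3.04) fell, while the lipoprotein receptor VLDLR rose by 7.04. Of 11 heat shock genes 6 fell and 1 rose, also over the list alone (median -1.57, adjusted p = 0.0263, and adjusted p = 0.413 with an estimated correlation). HSPB1 (-7.67), HSPE1 (-4.97) and HSP90AA1 (-5.06) fell and the small heat shock gene CRYAB rose by 7.36. The heat shock call ended under the filter at the 65th percentile and without PCLKC replicate 2. The lists of cholesterol synthesis (8 fell and 3 rose of 17, adjusted p = 0.0703), metallothioneins and oxidative stress (7 and 6 of 16, adjusted p = 0.453) and ribosomal proteins (10 and 7 of 21, adjusted p = 0.181) did not pass, with counts over the list alone that were equal. MSMO1 (-5.31), SC5D (-3.98) and TXNRD1 (-6.27) fell, and MT1G rose by 3.78. RPL35 rose by 3.07 and RPL37 by 2.88, and 2 further RPL37 probe sets passed in the opposite direction.

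Adhesion genes moved in both directions on the PCLKC arrays, whose hybridization controls read 54005 and 50185 against 4509 and 6496 on the parental arrays. Of 7 desmosome genes 5 fell and 0 rose, also over the list alone (median -3.32, adjusted p = 0.00655, and adjusted p = 0.413 with an estimated correlation). DSG2 (-6.18), DSP (-5.93), PERP (-5.92) and PKP2 (-2.40) were named by rule. Another PERP probe set passed in the opposite direction, and the other PKP2 probe set had the opposite sign without passing. Of 18 integrin and matrix genes 12 fell and 3 rose, also over the list alone (median -3.17, adjusted p = 0.00477, and adjusted p = 0.413 with an estimated correlation). ITGAV (-4.04), ITGA2 (-5.84) and CD151 (-4.46) fell, and the basement membrane collagen COL4A1 rose by 7.98, a size set in part by the pseudocount, as the parental arrays read it at 5.97 and 2.43. The adherens junction list had 5 lower and 3 higher of 15 (5 and 4 over the list alone, adjusted p = 0.334), and its relative median, -0.36, turned to 0.36 under quantile normalization. Its median log2 change was 0.47 and its mean -0.93, and those of the tight junction list were 0.14 and -0.73, with a camera direction of down for both. Beta-catenin, CTNNB1, rose by 4.33 ± 0.20 (adjusted p = 0.00199), a call that ended after hybridization-control scaling (log2 change 1.07, adjusted p = 0.0702), and P-cadherin, CDH3, fell by 5.91. Of the other CTNNB1 probe sets 1 rose too and 1 had the opposite sign without passing. E-cadherin, CDH1, fell by 4.67 ± 0.59 on its brighter probe set and rose by 1.53 on the other, both past the threshold. Tight junction genes had 6 lower and 3 higher of 17, also over the list alone (adjusted p = 0.229), where TJP1 rose by 2.52, with its other probe set of opposite sign and not past the threshold, and CLDN12 fell by 4.14. Brush border and microvilli genes had 7 lower and 3 higher of 15, also over the list alone (adjusted p = 0.118), where RDX fell by 3.95, with 1 other probe set past the threshold in the opposite direction, and VIL1 rose by 4.04. Fry, which tests a list without setting it against the other genes, passed lists that camera did not. Among them were brush border (fry adjusted p = 0.00707), adherens junction (0.0168), CDK inhibitor (0.0124), enterocyte (0.0131) and fibroblast genes (0.00712). The Wnt list did not pass by fry either (0.0852). Cadherins and protocadherins had 9 higher and 3 lower of 21 (9 and 4 over the list alone, adjusted p = 0.708), and their relative median, 0.39, turned to -0.49 under quantile normalization. CDH6 rose by 8.92 and FAT1 fell by 4.34.

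Wnt, Hippo and galectin genes did not pass as lists on these arrays, which differed in their hybridization controls (54005 and 50185 against 4509 and 6496). The camera direction was down for the Wnt list despite a median of 0.09 and a mean of 0.13, and down for the Hippo list with a median of 0.25 and a mean of -0.19. Of 23 Wnt/beta-catenin targets 6 rose and 6 fell, also over the list alone (adjusted p = 0.351). SOX4 rose by 3.45, with 1 of its other probe sets past the threshold in the opposite direction, and DKK1 fell by 3.03. MYC fell by 2.39 ± 0.51 (adjusted p = 0.0170) and CCND1 by 2.27 ± 0.35 (adjusted p = 0.00834), the latter on the brighter of 2 probe sets. AXIN2, a feedback target of the pathway, had a log2 change of -0.21 ± 0.28 (adjusted p = 0.545) on its brightest probe set, while 1 of its 3 others rose by 3.34. Of 17 Hippo/YAP targets 7 fell and 5 rose, also over the list alone (adjusted p = 0.462), where LATS2 rose by 2.52 and NT5E fell by 5.55. Of 7 galectins 3 rose and 2 fell, also over the list alone (adjusted p = 0.736), and the relative median, 0.21, turned to -0.37 under quantile normalization while the median log2 change was 1.04 and the mean -0.36. LGALS1 fell by 3.88 ± 0.24 (adjusted p = 0.00207) and LGALS14 rose by 3.62. LGALS3 rose by 1.04 ± 0.20 (adjusted p = 0.0138) as deposited, but had log2 changes of 0.57 (adjusted p = 0.0750) after quantile normalization, -0.47 (adjusted p = 0.133) after median centring and -2.22 after hybridization-control scaling (adjusted p = 0.000923).

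Among signalling and cell cycle lists, p53 targets and interferon genes passed as lower on the PCLKC arrays, whose Alu control read 914 and 2237 against 65784 and 69083 on the parental arrays. Of 20 p53 targets 10 fell and 3 rose, also over the list alone (median -2.66, adjusted p = 0.0119, and adjusted p = 0.413 with an estimated correlation). CCNG1 (-5.84), the death receptor TNFRSF10B (-6.43), RRM2B (-5.78) and GDF15 (-7.35) fell, and 1 other TNFRSF10B probe set passed in the opposite direction. Of 28 interferon response genes 13 fell and 4 rose (13 and 5 over the list alone; median -2.14, adjusted p = 0.0339, and adjusted p = 0.413 with an estimated correlation), among them IFITM3, IFITM2 (-7.91), IFI6 (-4.62) and IFIT1 (-3.92). The interferon call ended under the filter at the 65th percentile and without PCLKC replicate 2. Of 7 CDK inhibitors 2 fell, also over the list alone (adjusted p = 0.0503), CDKN1B (-4.54) and CDKN1A (-1.76). Of 25 G1/S and DNA replication genes 8 rose and 6 fell (8 and 7 over the list alone, adjusted p = 0.276), with SLBP (-3.95) and PCNA (-4.59) lower. Of 25 G2/M and mitosis genes 7 rose and 2 fell, also over the list alone (adjusted p = 0.654), where CDK1 rose by 2.98, with 1 other probe set past the threshold in the opposite direction, and PLK1 by 3.78. Their median log2 change was 0.75, which was -0.08 relative to all genes and 0.03 under quantile normalization. Immediate early and AP-1 genes had 9 higher and 6 lower of 21, also over the list alone (adjusted p = 0.972), with IER3 (-6.24) and IER2 (-4.46) lower. NF-kB and cytokine genes had 9 higher and 2 lower of 18 (11 and 3 over the list alone, adjusted p = 0.351), with TNF higher by 4.94 and IL6 by 4.24, from parental signals near the pseudocount.

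Of the markers of differentiation and of other cell types, the immune list alone passed, as higher, on the PCLKC arrays, on which the array median signal itself was 234 and 241 against 73.7 and 78.8 on the parental arrays. Immune cell markers had 8 higher and 0 lower of 11, also over the list alone (median 2.26, adjusted p = 0.0282, and adjusted p = 0.413 with an estimated correlation). CD163 (4.90), ITGAM (3.09), CSF1R (3.36) and MS4A1 (3.61) were among them, and the call ended under quantile normalization (adjusted p = 0.0730) and without PCLKC replicate 1. The parental arrays read CD163 at 6.16 and 4.90 and AGR2 at 6.46 and 6.18, below the pseudocount, on which the sizes of these rises depend. CD163, MS4A1 and the fibroblast marker DCN lay below the array median on the parental arrays and the array labelled GFP. MS4A1, for example, read 26.5, 46.7 and 44.6 there, with medians of 73.7, 78.8 and 57.9. Such markers passed the filter only through the PCLKC-carrying arrays and could scarcely be lower. The counts of 0 lower were thus partly fixed in advance. Fibroblast markers had 7 higher and 0 lower of 13 (8 over the list alone, adjusted p = 0.0703), with DCN higher by 4.92 and THY1 by 3.38. Only 2 endothelial markers were measured, which left that list untested; PECAM1 rose by 2.86 and KDR by 2.62. Mesenchymal genes had 8 higher and 0 lower of 15, also over the list alone (adjusted p = 0.0703), with VIM and SNAI2 (2.96) higher. Secretory lineage genes had 6 higher and 1 lower of 10, also over the list alone (adjusted p = 0.168), with AGR2 higher by 6.33 and SPDEF by 3.79. Enterocyte differentiation genes had 10 higher and 2 lower of 16 (11 and 2 over the list alone, adjusted p = 0.181), with the peptidase DPP4 higher by 5.61 and carbonic anhydrase CA2 lower (-2.49). After hybridization-control scaling TJP1, SNAI2, LATS2, CDK1, RPL35, RPL37, ITGAM, PECAM1 and KDR had log2 changes below 0.

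PCLKC-GFP versus the array labelled GFP repeated the comparison with 1 array on each side. IGFBP7 was higher by 13.59 ± 0.43 (log2 change ± SE), IRX5 by 12.28, HDGFL3 by 11.66, POU3F3 by 11.37 and CADM1 by 10.98. FAM3C was lower (-9.87 ± 0.52), as were the chaperonin HSPE1 (-9.62), the dynein light chain DYNLT1 (-9.01), LYPLA1 (-8.89) and the asparaginyl-tRNA synthetase NARS1 (-8.82). Each of these 10 genes had an adjusted p of 0.00888. The array labelled GFP read IGFBP7 at 7.77, IRX5 at 7.30 and HDGFL3 at 1.90, below the pseudocount, so sizes and order depend on it: IGFBP7 was higher by 12.30 with the larger pseudocount and by 14.89 without one. The PCLKC-GFP array read FAM3C at 8.53 and LYPLA1 at 11.9, so the sizes of the falls depend on it too. CDHR2 itself was higher by only 2.58 ± 0.52 (adjusted p = 0.0284), and by log2 -2.20 (adjusted p = 0.0146), thus lower, after hybridization-control scaling. The CDHR2 call also ended after median centring (0.71, adjusted p = 0.335) and without the mean-variance trend (2.58, adjusted p = 0.0557). CTNNB1 was higher by 4.36 ± 0.29 (adjusted p = 0.00888; -0.43 after hybridization-control scaling, adjusted p = 0.610), LGALS1 lower (-4.40) and CDH1 lower on its brighter probe set (-4.78), with its other probe set past the threshold in the opposite direction. CCND1 was lower (-3.51, adjusted p = 0.0166), LGALS3 higher (2.16, adjusted p = 0.0152; -2.62 after hybridization-control scaling), MYC had a log2 change of -2.54 (adjusted p = 0.0532) and AXIN2 of -0.17 (adjusted p = 0.751). In total 11625 probe sets differed, 7244 higher and 4381 lower, with the lone arrays assumed to vary like the duplicated groups. The share of higher calls was 62.3% as deposited, 41.1% after quantile normalization, 9.89% after median centring and 0.41% after hybridization-control scaling. The count was 0 without parental replicate 1 or 2, 26508 without PCLKC replicate 1 and 26540 without PCLKC replicate 2.

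The desmosome, G1/S, oxidative phosphorylation, CDK inhibitor and G2/M lists had the lowest medians relative to that of all genes, 0.89, in this comparison, whose list values come from 1 array on each side. The hybridization controls read 100564 on its PCLKC-GFP array and 3651 on the array labelled GFP. Lists of this comparison were planned as values and not as tests. Relative medians were -5.29 for the 7 desmosome genes, -4.17 for the 25 G1/S genes and -3.63 for the 24 oxidative phosphorylation genes. They were -3.59 for the 7 CDK inhibitors and -3.14 for the 25 G2/M genes. The array labelled GFP, the other side here, had all 25 genes of the G1/S and of the G2/M list above the parental arrays (relative medians 2.59 and 3.52), while PCLKC versus parental had 7 G2/M genes higher and 2 lower.

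Fibroblast markers, 13 of them measured, had a relative median of 2.72 in PCLKC-GFP versus GFP. The median log2 change of all probe sets here was 0.97 as deposited and -3.40 after hybridization-control scaling, so the direction of a change depends on the scaling. Markers that passed the filter only through PCLKC-carrying arrays, such as DCN, could also scarcely be lower. Relative medians were -2.88 for heat shock, -2.45 for integrin and matrix and -2.05 for stress response genes. They were -2.32 for p53 targets, -1.75 for cholesterol synthesis and -1.39 for hypoxia and glycolysis genes.

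The 3 arrays labelled PCLKC or PCLKC-GFP against the other 3, among them the array labelled GFP with its CDHR2 signal of 4831, formed the only fit whose spread held differences between lines of a side. On each side 2 of the 3 arrays carry the same line label and were taken as independent. The spread therefore mixes differences within and between lines, and its p-values overstate the evidence about lines. IGFBP7 rose by 13.03 ± 0.35, STC1 by 12.10 ± 0.54, HDGFL3 by 11.51, POU3F3 by 11.25, CADM1 by 11.22, PRORSD1P by 10.56 and IRX5 by 10.28. TMEFF2 rose by 9.51, the kidney cadherin CDH6 by 8.84 and VIM by 8.78 ± 0.85. COX1 (-9.78 ± 0.97), FAM3C (-9.71), IFITM3 (-8.47), MTHFD2 (-8.39), the mitochondrially encoded ATP6 (-8.15), NDUFC1 (-7.94), CYCS (-7.78), the lysosomal LAMP1 (-7.76), ATP5MJ (-7.67) and EIF3L (-7.67 ± 1.11) fell. Adjusted p-values of these 20 genes lay between 5.82e-07 and 0.000542, and the naming rule took only genes whose sides did not overlap. The other 3 arrays read IGFBP7, STC1 and HDGFL3 at 1.90 to 12.8, so these sizes depend on the pseudocount, with 11.85, 10.64 and 9.96 under the larger one and 14.08, 13.96 and 13.79 without one. Falls of COX1 and FAM3C depend on it too, with PCLKC-carrying arrays as low as 10.5 and 8.53, and COX1 at -9.01 and -10.40 under these settings. The other probe set of TMEFF2 and that of CYCS had the opposite sign without passing. Counts over all probe sets were 14851 higher and 7748 lower, 22599 in total. The higher share was 65.7% as deposited, 47.2% after quantile normalization, 26.8% after median centring and 1.63% after hybridization-control scaling.

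Of the gene lists 13 passed the camera test in this comparison, 11 of them lower and 2 higher. Camera does not match a list with other genes of like signal, and the 2 sets of arrays correlated at only 0.261 to 0.304. Lists bright on the other arrays could therefore fall, and dim lists rise, whatever their function. Random lists matched on mean signal were not run for these 13 lists. Desmosome (relative median -3.92, 5 of 7 lower and 0 higher, adjusted p = 0.00550), integrin and matrix (-2.94, 12 of 18 lower and 3 higher, adjusted p = 0.00893) and oxidative phosphorylation genes (-2.82, 16 of 24 lower and 0 higher, adjusted p = 5.08e-07) were lower. So were p53 targets (-2.44, 10 of 20 with 4 higher, adjusted p = 0.0113), stress response (-2.30, 15 of 26 with 3 higher, adjusted p = 0.00535), hypoxia and glycolysis (-2.12, 12 of 24 with 3 higher, adjusted p = 0.00535), heat shock (-2.01, 6 of 11 with 1 higher, adjusted p = 0.0253) and interferon genes (-1.90, 10 of 28 with 4 higher, adjusted p = 0.0419). G1/S genes (-2.63, 10 of 25 with 3 higher, adjusted p = 0.0113), CDK inhibitors (-2.27, 3 of 7 with 0 higher, adjusted p = 0.0344) and cholesterol synthesis genes (-1.70, 8 of 17 with 2 higher, adjusted p = 0.0253) were lower, and fibroblast (2.08, 8 of 13 higher and 0 lower, adjusted p = 0.0299) and immune markers (1.54, 7 of 11 higher and 0 lower, adjusted p = 0.0494) were higher. The array labelled GFP, on which all 25 G1/S genes read above the parental arrays, is on the other side here; against the parental arrays alone the PCLKC arrays had 8 G1/S genes higher and 6 lower (relative median -1.10, adjusted p = 0.276). The calls of G1/S, CDK inhibitor, cholesterol synthesis, fibroblast and immune lists ended under quantile normalization. Under the filter at the 65th percentile these 5 ended as well, with those of the interferon and heat shock lists, and the interferon or immune call ended on leaving out each parental or PCLKC array. The immune call also ended with the pseudocount of 38.8. After hybridization-control scaling 388 of 23867 calls over all probe sets were higher, so the counts of higher markers depend on the scaling. Markers below the median on the other arrays also passed the filter only through PCLKC-carrying arrays, which partly fixed their counts of 0 lower. With an estimated correlation the 13 lists had adjusted p-values between 0.236 and 0.638. The estimated correlation was 0.700 for the G1/S and 0.175 for the oxidative phosphorylation list, so correlation bears on their p-values too. It was below the preset 0.01 for the heat shock, p53, fibroblast and CDK inhibitor lists. Adjusted over the list alone, the counts were the same except for heat shock (2 higher in place of 1), interferon (9 lower), oxidative phosphorylation (18 lower) and CDK inhibitors (2 lower).

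**Figure D2:**
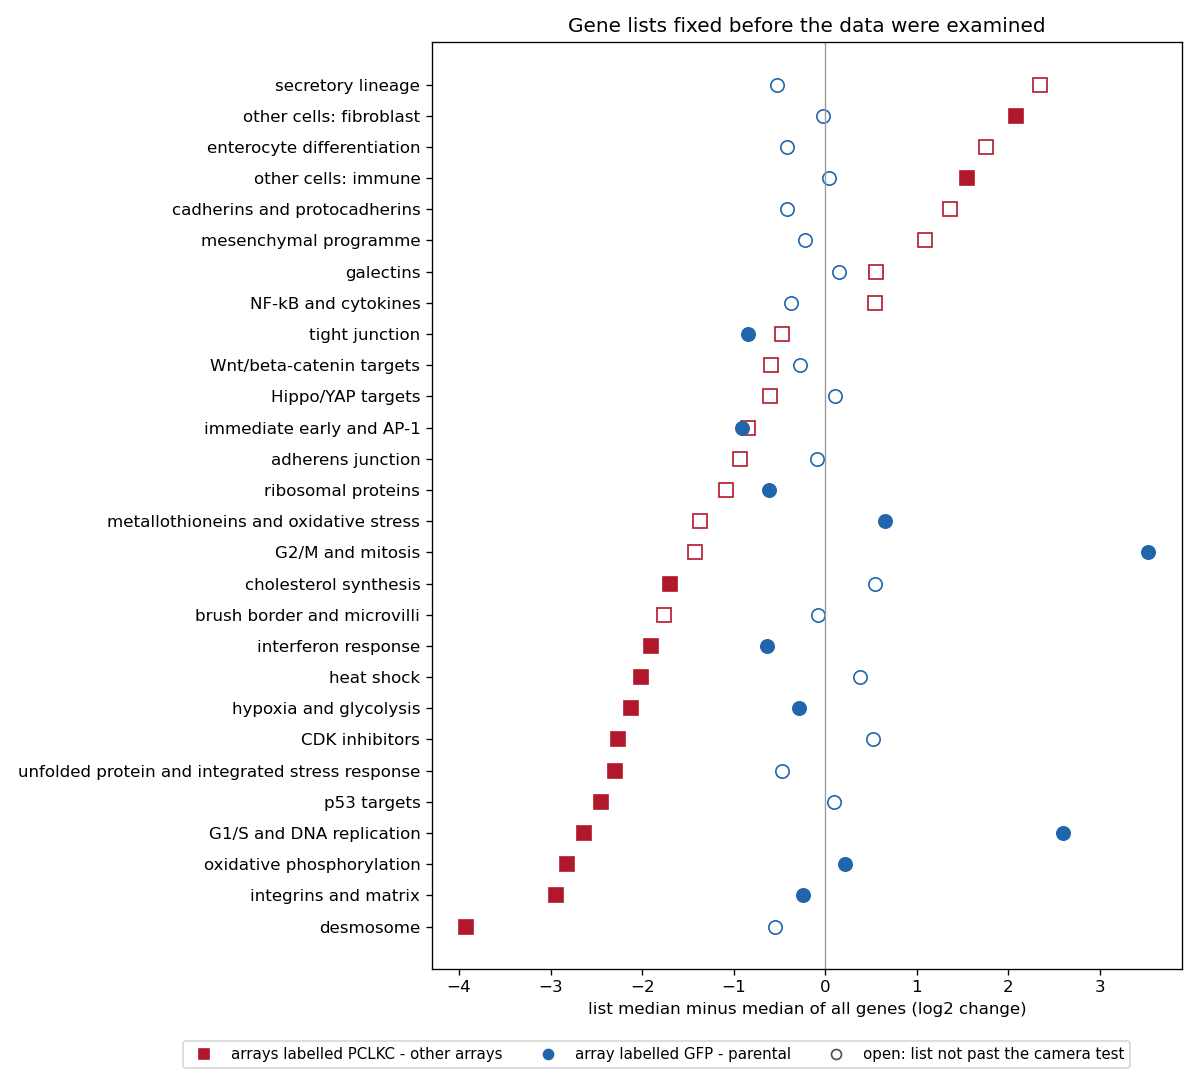
Median log2 change of each gene list minus the median of all genes, for the arrays labelled PCLKC or PCLKC-GFP against the others (red squares, 3 against 3) and the array labelled GFP against the parental arrays (blue circles, 1 against 2); filled symbols passed the camera test with a preset correlation. The desmosome list lies lowest in the PCLKC comparison at -3.92 and the G2/M list highest on the array labelled GFP at 3.52, while the galectin list of the PCLKC comparison (0.56) turned to -0.36 under quantile normalization, as the brush border and fibroblast lists of the array labelled GFP changed sign near 0 under other scalings.

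The PCLKC effects of the lines with and without GFP share no array and could be set side by side. Both set arrays with bright hybridization controls against dimmer ones (54005 and 50185 against 4509 and 6496, and 100564 against 3651). A difference between arrays that both share could give agreement with or without an effect of PCLKC. The array labelled GFP also read CDHR2 at 4831. After hybridization-control scaling 3.25% and 0.41% of the calls were higher, so the shared higher count below holds for the deposited signals. Across 16088 genes, which are not independent replicates, the log2 differences PCLKC minus parental and PCLKC-GFP minus GFP had a Pearson correlation of 0.826 and a Spearman correlation of 0.822, and 84.9% had the same sign. Of the genes called in each comparison 3175 were higher in both, where independent lists would share 1322, and 1763 were lower in both, where independent lists would share 455. Only 32 genes were called in opposite directions. The difference between the 2 effects itself gave 0 calls with limma, 4614 probe sets at an unadjusted p under 0.05, and a smallest adjusted p of 0.303. Named by smallest p, as none passed, were RRM2 (6.99 ± 0.49), a subunit of ribonucleotide reductase, NDUFA1 (6.57 ± 0.56) and the mitotic kinase AURKA (5.82 ± 0.54) on the positive side, each not past the threshold. On the negative side were COX1 (-5.42 ± 0.46), EPB41L4A-AS1 (-5.11 ± 0.53), an antisense transcript, and the glutamate transporter SLC1A3 (-5.03 ± 0.55), also not past it. Without PCLKC replicate 1 this contrast gave 9031 calls and without PCLKC replicate 2 it gave 9040, where the spread came from the parental pair alone.

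Among the gene lists, those of the cell cycle had the largest median differences between the array labelled GFP and the parental arrays. Single genes of other kinds, such as CDHR2, differed as much. The median log2 change of all probe sets was -0.17 as deposited, 0.17 after median centring and 0.37 after hybridization-control scaling. The split into higher and lower calls therefore depends on the scaling. The 4-group fit, which takes its spread partly from the PCLKC pair, gave 0 calls with limma, 3520 probe sets at an unadjusted p under 0.05, and an adjusted p of 0.276 for the 6 genes the rule named. These were RRM2 (4.81 ± 0.35), the anaphase activator CDC20 (4.74 ± 0.37) and CDHR2 (5.76 ± 0.45) on the positive side, and BCL6 (-3.85 ± 0.26), LEMD1 (-4.31 ± 0.34) and CPEB2 (-3.98 ± 0.34) on the negative side. The counts were 5808 without PCLKC replicate 1 and 5892 without PCLKC replicate 2. A fit of the 3 arrays alone, chosen after the data were seen, gave 8305 probe sets, 3185 higher and 5120 lower on the array labelled GFP, which was assumed to vary like the parental pair. In it 1818 genes were higher and 2373 lower.

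In the fit of the 3 arrays alone, all 25 measured G2/M and mitosis genes and all 25 G1/S and DNA replication genes were higher on the array labelled GFP, over all genes and adjusted over the list alone. That array also differed from the parental arrays in the 3' to 5' ratio of ACTB (1.16 against 2.22 and 2.02), the mitochondrial median (12380 against 40322 and 42953) and the Alu control (39045 against 65784 and 69083). The G2/M list had a median 3.52 above that of all genes (adjusted p = 3.03e-29) and the G1/S list 2.59 (adjusted p = 3.66e-23), and each had an adjusted p of 0.679 with an estimated correlation. Named after their values were seen, CCNB1 was higher by 3.86 ± 0.14, PLK1 by 4.47, the transcription factors MYBL2 by 6.12 and FOXM1 by 4.30, and MCM5, a subunit of the replicative helicase, by 3.87. CCNB1 read 17850 against 1195 and 1242 on the parental arrays. The parental arrays read MYBL2 at 12.3 and 19.2, near the pseudocount of 11.24, on which the size of its change depends. The median of the G2/M list remained above 0 as deposited (3.40) and under quantile normalization (2.81), median centring (3.74) and hybridization-control scaling (4.02). Metallothionein and oxidative stress genes (7 of 16 higher and 2 lower, 8 and 2 over the list alone, relative median 0.65, adjusted p = 0.00972) and oxidative phosphorylation genes (9 of 24 higher, 10 over the list alone, 0.22 and only 0.03 under quantile normalization, adjusted p = 0.0277) also passed. Their adjusted p was 0.679 with an estimated correlation.

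Lower on the array labelled GFP in the same fit were tight junction, interferon, immediate early and ribosomal protein genes. Tight junction genes had 9 of 17 lower and 0 higher (12 over the list alone; relative median -0.84 and -0.85 under quantile normalization, adjusted p = 0.000188), with CLDN3 at -2.42 and OCLN at -1.54. Interferon response genes had 10 of 28 lower and 3 higher, also over the list alone (-0.64 and -0.42 under quantile normalization, adjusted p = 0.00972), with IFITM1 (-4.63 ± 0.14) and BST2 (-4.29 ± 0.40) lower. Immediate early genes had 11 of 21 lower and 1 higher (15 and 1 over the list alone; -0.91, adjusted p = 2.60e-05), with SPRY4 at -2.81. Ribosomal protein genes had 12 of 21 lower and 0 higher (20 over the list alone; -0.62 and -0.32 under quantile normalization, adjusted p = 1.54e-05). Hypoxia and glycolysis genes (10 of 24 lower and 1 higher, 11 and 1 over the list alone, -0.29, adjusted p = 0.0277) and integrin and matrix genes (7 of 18 lower and 1 higher, also over the list alone, -0.24, adjusted p = 0.0470) passed too. For each of these 6 lists the adjusted p was 0.679 with an estimated correlation. Of the genes always named, CTNNB1 had a log2 change of 0.41, MYC of -0.49, CCND1 of 1.08, AXIN2 of 0.28, CDH1 of -2.12, LGALS1 of 0.79 and LGALS3 of -0.56, none past the threshold of the 4-group fit. In the fit of the 3 arrays alone CDH1 (adjusted p = 0.000294), CCND1 (adjusted p = 0.00794), LGALS1 (adjusted p = 0.0306) and LGALS3 (adjusted p = 0.0430) passed, and CTNNB1, MYC and AXIN2 did not.

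**Figure D3:**
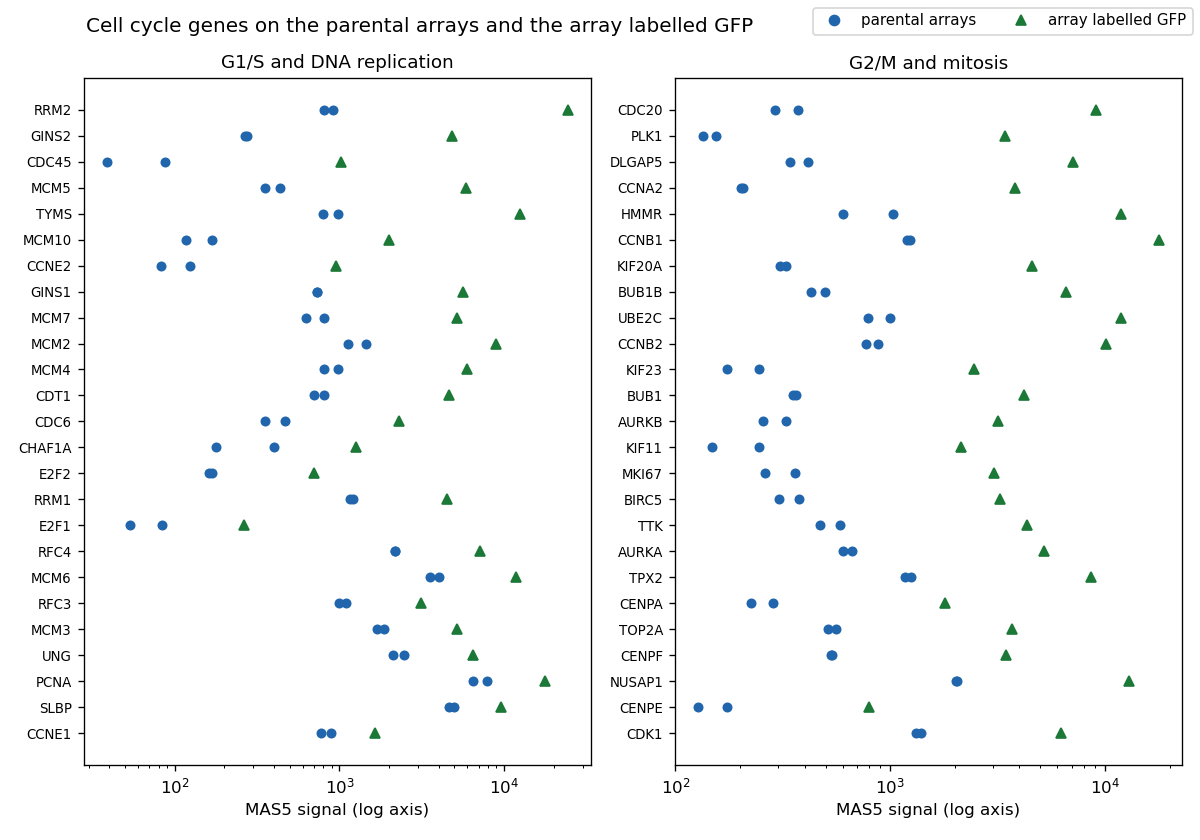
MAS5 signal, on log axes, of each measured gene of the G1/S and DNA replication list (left) and the G2/M and mitosis list (right) on the 2 parental arrays (circles) and the array labelled GFP (triangle). The triangle lies to the right of both circles for every gene of both lists.

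PCLKC-GFP versus PCLKC, 1 array against 2, gave 0 calls with limma and 5514 probe sets at an unadjusted p under 0.05. The 6 genes named by rule had an adjusted p of 0.160. Higher on the PCLKC-GFP array were COX1 (3.98 ± 0.33), HTATSF1 (4.43 ± 0.44) and NT5C2 (3.84 ± 0.40), and lower were NDUFA1 (-6.77 ± 0.39), HSPE1 (-4.25 ± 0.31) and the co-chaperone FKBP4 (-3.87 ± 0.30). The other probe set of HTATSF1, that of NT5C2 and 2 of the 3 others of FKBP4 had the opposite sign without passing. Without PCLKC replicate 1 the comparison gave 9949 calls and without PCLKC replicate 2 it gave 10388, with each remaining lone array assumed to vary like the parental pair.

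The differences PCLKC minus parental and GFP minus parental share the parental arrays. Their Pearson correlation across genes was 0.113 and their covariance 0.289, against 0.220 and 0.0766 in 100 simulations of unchanged groups with the same parental pair, so that the covariance exceeded the simulated one by 0.213. With 2 parental arrays the controls could not be split into separate sets of 2, so part of the covariance may come from the shared controls.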

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

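Tests chosen only after the result was seen were those of the Alu control, hybridization-control scaling, oppositely called probe sets, carry-over, label swap, construct, array scaling, RNA quality and cycling cells; the others were chosen before, but how the parts of the test of transcript levels through PCLKC alone combine was rewritten after their values were seen.

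Control probe sets outside the comparisons differed between the arrays of PCLKC-carrying lines and the parental and GFP arrays, in both directions. The hybridization controls were 13.7-fold higher with PCLKC (geometric means, 3 arrays each), the poly-A controls 9.97-fold and the 18S rRNA control 24.5-fold, while the Alu control was 29.9-fold lower. Poly-A controls ranged from 2060 to 51467 on the PCLKC-carrying arrays and from 747 to 1309 on the others.

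The first pattern is that the arrays of PCLKC-carrying lines stand apart, with 22599 probe sets past the threshold. A change of transcript levels through PCLKC alone was argued against, as the sole cause, by the hybridization controls, which are added to each sample. They read 50185 to 100564 on the PCLKC-carrying arrays and 3651 to 6496 on the others, though no bound had been set for them. A part played by PCLKC stays open. The disagreement between paired probe sets of a gene repeated in separate arrays with a correlation of 0.707, above the bound set against it. That bound was wrong by design, since probe sets of unequal response repeat their disagreement in a true change too. The correlation between their changes, 0.424 against 0.555 for GFP minus parental, was within the bound set for it. Of genes with both probe sets called, 22.5% were called in opposite directions, against 3.59% in the fit of the parental and GFP arrays alone. That share, 6.27 times as large, does not decide, as the fits differ in form. RNA from a non-primate species stays open as well, since the Alu control changed by -4.11 on the least changed PCLKC array. Dim or degraded target was not settled by its tests: 36 probe sets were bright on the PCLKC arrays alone, within its bound, and 16 were over 16 times higher after hybridization-control scaling, between its bounds. The hybridization controls were 13.7-fold brighter at the same trimmed mean, as a larger rescaling of a dim target would give. The highest signals go with this too, at 598766 to 1103780 on the PCLKC-carrying arrays and 57208 to 112145 on the others. Dim and degraded target could not be told from each other. Of the 10 splits of the arrays into 3 and 3, 1 gave as many probe sets, the real split with 22599 against at most 0 in the others, and 10 splits are too few for a share under 0.05.

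The second pattern is the CDHR2 signal on the array labelled GFP. Carry-over of RNA from a PCLKC line was argued against by 41 probe sets bright on all PCLKC arrays, whose median log2 change on the array labelled GFP was -0.31. That holds only as far as their signals come from RNA of the PCLKC lines, which a dim target would leave in doubt. A swap of the labels PCLKC-GFP and GFP was argued against by CDHR2 itself, 8.34 above parental (log2) on the PCLKC-GFP array. Construct sequence in the line labelled GFP stays open: 6 probe sets, CDHR2 among them, were over 16 times above both parental arrays on all stable lines, but nothing in the labels gives the construct. A single wrong label stays open too, and no biological explanation was tested.

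The third pattern is that cell cycle genes were higher on the array labelled GFP than on the parental arrays. Scaling of the arrays was argued against by the G2/M list, whose lowest median log2 change under the other scalings was 2.81. A difference in RNA quality cannot be told apart: the list lay at percentile 100 of 10000 random lists, but these were matched on mean signal and not on quality, and the ACTB 3' to 5' ratio was 1.16 against 2.22 and 2.02. A larger share of cycling cells stays open. The G1/S list had a median of 2.47, but its genes are part of the pattern, so this value cannot decide. With 1 array in that group, a difference between lines or between cultures stays open as untested.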

How the results depend on the processing

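Hybridization-control scaling and the fit of the parental and GFP arrays alone were the alternatives chosen only after the result was seen. Among 162 results for named genes 23 were the same in every alternative; of the values under alternatives 1966 were the same, 247 lost and 70 gained their side of the threshold and 14 reversed. Signal over background limits dim probe sets, with 10th percentiles of 4.74 to 33.7. The cause was not tested unless given.

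Quantile normalization gave 5874 probe sets in PCLKC-GFP versus GFP (2416 higher), an agreement of the PCLKC effects of 0.783 and a CDHR2 change of 6.79 against 7.92. With 1 probe set per gene fewer features were tested, with 9479, 6395 and 10265 calls in PCLKC versus parental, PCLKC-GFP versus GFP and the fit of 3 against 3. The agreement was 0.801 without a filter and 0.846 with a filter at the 65th percentile, which called 6 lists in the fit of 3 against 3. Hybridization-control scaling gave 23266 probe sets in PCLKC-GFP versus GFP (95 higher), 89 for the difference of effects, 150 in GFP versus parental, 1 in PCLKC-GFP versus PCLKC, 15 lists, an agreement of 0.845 and a CDHR2 change of 4.79. The parental and GFP arrays alone gave 8305.

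Leaving out 1 array at a time gave 0 to 27911 probe sets in PCLKC versus parental, 0 to 26540 in PCLKC-GFP versus GFP, 0 to 9040 for the difference of effects, 0 to 5892 in GFP versus parental, 0 to 10388 in PCLKC-GFP versus PCLKC and 18452 to 22037 in the fit of 3 against 3. The agreement was 0.795 to 0.819. Lone arrays were then assumed to vary like the remaining pair.

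LGALS3 in PCLKC versus parental reversed to -0.47 under median centring. Under hybridization-control scaling the log2 changes in PCLKC versus parental were LGALS3 -2.22, TJP1 -0.74, SNAI2 -0.21, LATS2 -0.74, CDK1 -0.27, RPL35 -0.20, RPL37 -0.39, ITGAM -0.00464, PECAM1 -0.33 and KDR -0.36; in PCLKC-GFP versus GFP they were CDHR2 -2.20, CTNNB1 -0.43 and LGALS3 -2.62. A replicate block gave 20556 probe sets, but same-numbered deviations had a correlation of 0.00675 over 2 pairs, so the numbers do not pair the arrays. Other CDHR2 probe sets were not run, as there is only 1.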

Other observations

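The test of the kidney list was chosen before its result was seen, and the genes named here were chosen only after the result was seen.

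Besides CDHR2, 5 probe sets were over 16 times above both parental arrays on all 4 arrays of stable lines. They were a pair for RAP1A, a small GTPase, and those of MYBL2, B9D1 and a transcript without a gene name. The brighter RAP1A probe set read 45461, 29630 and 64943 on the PCLKC and PCLKC-GFP arrays, 10128 on the array labelled GFP, and 8.4 and 36 on the parental arrays. RAP1A as a gene did not follow: its probe set that was bright on every array differed by -0.22 (log2, adjusted p = 0.593) between PCLKC and parental arrays, and the fourth by 1.70 (adjusted p = 0.0656).

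On the array labelled GFP, in the fit with the parental arrays alone, SERPINA3 (-5.67 ± 0.28, log2 change ± SE) and SERPINF1 (-4.84 ± 0.31) were lower. So were the acyl-CoA synthetase ACSL5 (-5.28 ± 0.16) and the nuclear RNA MALAT1 (-4.60 ± 0.16). DHRS2 (4.93 ± 0.42) and IGFBP6 (4.29 ± 0.16) were higher. The array labelled GFP read SERPINA3 at 14.2 and SERPINF1 at 15.2, near the pseudocount of 11.24, on which the sizes of these falls depend.

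A hypothesis was that kidney-derived cells contributed to the PCLKC-carrying arrays. The kidney list (15 of 20 genes measured, 14 higher and 0 lower) had a median log2 change of 3.21 in the fit of 3 arrays against 3, at percentile 99.3 of 10000 random lists matched on mean signal; its most abundant gene was AQP2, and 4 genes lay above the parental median. The neuron list stood nearly as high (3.03, percentile 97.8), while liver (2.07, 44.0) and lung (1.72, 40.5) did not, so the test may not be specific to kidney. A gene below the median on the other arrays passed the filter only through PCLKC-carrying arrays, which partly fixed the count of 0 lower. The test also did not address the Alu control, 29.9-fold lower on these arrays, or the mitochondrially encoded genes, 176-fold lower. The labels name HCT116 alone.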
